A study of Homo sapiens with 9 samples.

How the data were processed

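Whole blood of children with a kidney transplant was collected in tubes that stabilise RNA at the draw, and total RNA was hybridised to Affymetrix HG-U133 Plus 2.0 arrays, with 1 biotin-labelled sample per array, per the labels' protocols. Each array gives 54675 probe sets, which are sets of short oligonucleotides read out as a single value. The deposited values are on the log2 scale and were made by the authors with GCRMA, per the submitters' processing notes. GCRMA corrects background with the help of probe sequence and summarises the probes of a set. Its version and settings are not given in the sources used here. The sorted probe set values differed between arrays, which does not tell whether the arrays were brought to a common scale before the probes were summarised. Whether the authors did so is unknown. A difference in scale between arrays enters every SD and score below unless a scaling alternative removes it. The deposited log2 values ran from 2.35 to 16.67, and 31.3% to 34.0% of the probe sets of an array sat at the lowest value, so levels near 2.35 have no order. Arrays carry no read depth, and the precision is limited by their number.

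The labels put 9 samples in 1 group, patients with a stable transplant, numbered as separate patients 1 to 9. The p-values for spread set a gene's variance against that of genes at a like level, and the others test association across the patients. With 1 array per patient, none of them separates the patient from the sampling, RNA preparation or array. The design text speaks of 24 patients, and the others were not analysed here. With 1 group there was no contrast to fit, and what was tested was the spread between patients, whether genes of a list moved together, and how list scores related to each other and to array quality.

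Probe sets were named through a table of the platform's 2016 annotation, with symbols updated through the gene identifiers of a RefSeq table of the GRCh38.p14 assembly, used for names only. Of the probe sets, 42898 were listed in that annotation, 41097 with 1 gene and 1801 with several, and 11777 were not listed. Of those with 1 gene, 41043 matched the RefSeq table. Genes of the Y chromosome, XIST and genes whose level can read a person's deletion, copy number or tissue type were left out, which removed 193 probe sets of 107 genes. Each of the 19668 remaining genes was represented by its probe set with the highest mean over the 9 arrays, and 6409 genes with a mean log2 value of at least 5 were used.

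Excess spread was tested with limma 3.58.1 in R 4.3.3. An intercept was fitted to each gene, the variance prior was estimated with a trend on level and a robust fit, and each gene's variance was referred to the upper tail of an F distribution with Benjamini-Hochberg adjustment at 0.05. In simulated data with the same 6409 genes, each gene was given an SD drawn from the fitted prior at its level. That drawn SD was then multiplied by 2 in 100 genes and by 4 in another 100. This test recovered 0% of either set and made 0 false calls. Larger multiples were not simulated.

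A set of 22 gene lists, holding 239 genes, was fixed before the data were examined, as were the pairs of lists, the rule for named genes, the tests and most alternatives. Of these genes, 216 were measured and 154 reached the level minimum, and 16 lists had the 3 or more members needed for a score. The lists covered blood cell types (neutrophil, neutrophil granule precursor, monocyte, T cell, cytotoxic and NK cell, B cell, plasma cell, erythroid, platelet, eosinophil, basophil and dendritic cell), responses (interferon, glucocorticoid, immediate early, heat shock, NFAT cytokines, proliferation) and MHC class II pathway, ribosomal protein, oxidative phosphorylation and reference genes. The median SD of a list and the mean Pearson correlation between its members were each placed as a percentile among 10000 random lists of the same size, drawn for each member from the 200 genes nearest in level. These percentiles describe the samples and are not p-values. A list score is the mean over members of the log2 value minus the gene's mean over the 9 patients.

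Relations between scores used Pearson's r and Spearman's rho with 2-sided exact tests over all 362880 pairings of 9 patients, and the smaller tail was doubled, as scipy 1.17.1 does. That convention was adopted after a first pass had counted absolute r, because simulated data showed it to differ from scipy, and the same pairs passed under both. Of 12 fixed pairs 11 could be tested, and Benjamini-Hochberg adjustment ran over those. Each r was computed again without the 2 patients farthest from the median of the first list. Where a covariate or score was removed, the residuals were permuted. The exact permutation p is then approximate and takes no account of that fit. List scores were also set against RNA integrity, measured as the log2 difference between the 3' and 5' probe sets of the GAPDH and ACTB controls, averaged over these 2 genes. In simulated data with 3 lists made to move together, all 3 exceeded the 95th percentile of coherence, as did 1 of 13 lists left as random.

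The named genes are the member with the largest and, for lists in a pair, the smallest SD of each list, and every NFAT cytokine. The rule also allowed the 12 genes of largest SD among those with excess spread. As none was called, the 12 genes with the largest SD are given instead, a choice made after the values were seen, and other members are named as examples of counts. Also added after seeing the data were the agreement of a gene's 2 highest probe sets, the level of the 7 hybridization spike-in probe sets as a covariate, the genes adjusted over each list alone, removal of the neutrophil and monocyte scores from the glucocorticoid with T cell relation, scores of the plasma cell and proliferation lists over all measured members and over those at the level minimum, and the SD of genes without a patient far from the others. Alternatives covered the level filter, the choice of probe set, leaving out probe sets with names ending in _x_at or _s_at, and scaling between arrays. They also covered a pseudocount, the variance prior, covariates, the score and leaving out each patient. No batch is named in the labels. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for the remaining steps.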

Results

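Gene expression was measured in the whole blood of 9 children with a stable kidney transplant, 1 array per patient. The study set stable patients beside patients with acute rejection. Only the stable group was analysed here, and no comparison with rejection was made. The data therefore answer how far blood expression differed between patients who share 1 clinical state, and which fixed gene lists varied most.

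No pair of arrays held identical values. Pearson's r between arrays, taken across the 6409 genes used, ran from 0.816 to 0.960 with a median of 0.926, and across all probe sets from 0.950 to 0.987. Genes are not independent replicates in such an r. Patient 7 had the lowest mean r with the other arrays, 0.883. The median level of the genes used lay between 6.80 (patient 1) and 7.23 (patient 7), a difference of 0.43 on the log2 axis. Over all probe sets the median, near the lowest value, ran the other way, from 2.46 in patient 7 to 2.52 in patient 1. The upper quartile was lowest in patient 1 (4.48) but highest in patient 3 (4.71), with patient 7 at 4.65. The 0.43 therefore cannot be read as a uniform difference in scale. The 7 hybridization spike-ins, bacterial RNAs added to every sample, averaged between 9.15 (patient 7) and 10.42 (patient 4). Spike-in level ran opposite to the median level of the genes (r = -0.80, exact permutation p = 0.0106; rho = -0.80, exact permutation p = 0.0138; n = 9).

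The 12 genes of largest SD were chosen after their values were seen, and no theme was tested among them. CD177, a neutrophil surface protein with a close pseudogene copy, had a mean log2 level of 5.19 ± 3.30 (SD, n = 9) and ranged from 2.76 to 12.84. Without patient 7 its SD was 1.75, which ranked 20, but its mean was 4.24, under the level minimum. CD177 was thus among the genes used only through that patient. The granule proteins LTF (lactoferrin, 7.56 ± 2.36) and LCN2 (lipocalin, 6.99 ± 2.28), the neutrophil enzyme ARG1 (arginase, 5.57 ± 2.24), the folate-binding protein FOLR3 (7.20 ± 2.46) and the elastase inhibitor PI3 (8.22 ± 2.05) were also among them. IFI27, an interferon-induced gene, stood at 6.30 ± 2.62, and JCHAIN, the chain that joins secreted IgM and IgA, at 7.38 ± 2.52. IGLC1, an immunoglobulin light chain gene, stood at 11.57 ± 2.28. Near-identical light chain genes exist, and whether its probe set reads them too was not checked. The embryonic globin HBZ (6.65 ± 2.49), the tubulin TUBB2A (7.41 ± 2.29) and the membrane protein TMEM176B (7.86 ± 2.21) completed the set.

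The SD of the median gene was 0.42, with a 5th to 95th percentile range of 0.18 to 0.93. An SD above 1 was seen in 235 genes. The spike-ins had SDs of 0.42 to 0.57, which can hold both hybridization and array scale, and they set no bound on the part of a gene's spread that arises in sampling and RNA preparation. In limma's test of excess spread 0 of 6409 genes passed the adjusted threshold, and 230 had an unadjusted p under 0.05. CD177 had a limma p of 0.000615 (adjusted p = 0.951). The test recovered none of the simulated genes whose drawn SD was multiplied by 2 or 4, so its 0 calls do not show that spread of that size was absent. Adjusted over the list alone, 16 of 154 members of the fixed lists passed in limma, in 5 lists, of which 1 (proliferation) held a single member, so that nothing was adjusted there. This adjustment is milder in shorter lists, and nothing was adjusted over the lists. CAMP passed with a limma p of 0.0184 in a list of 3 members used. GZMH, with a limma p of 0.00621, did not pass in a list of 11. Passing over the list alone therefore does not rank the lists or their genes. Over all lists 56 members had an unadjusted limma p under 0.05.

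**Figure D1:**
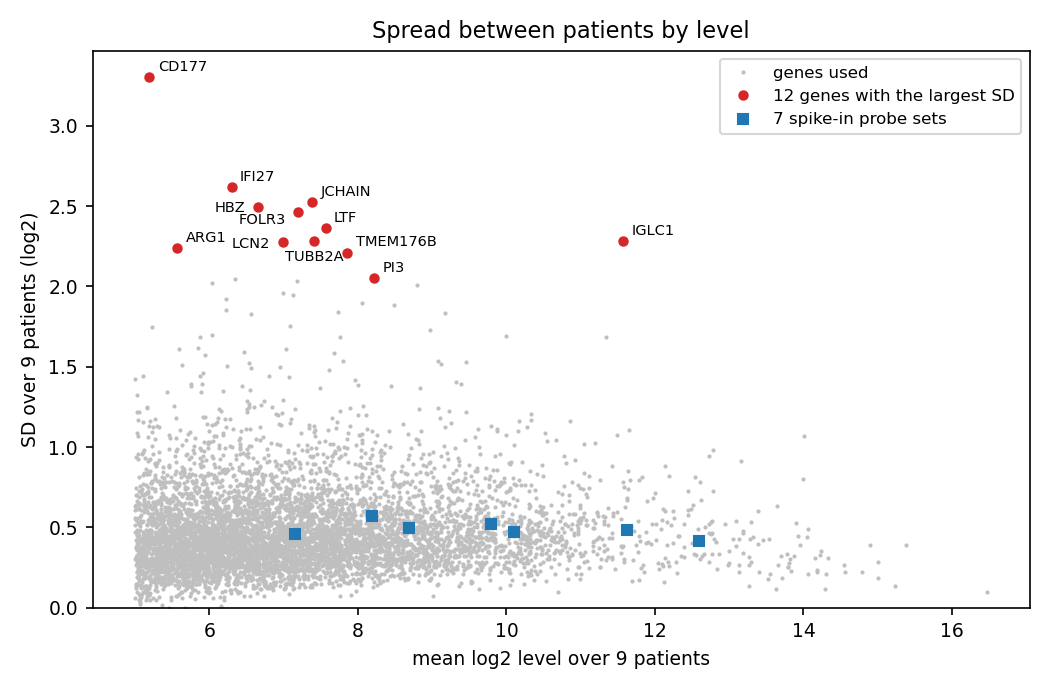
SD over 9 patients (vertical axis, log2) against mean log2 level (horizontal axis) for the 6409 genes used (grey points), the 12 genes of largest SD (red, named) and the 7 spike-in probe sets (blue squares). The named genes have SDs of 2.05 to 3.30, and the spike-ins 0.42 to 0.57.

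Interferon-induced genes varied together. The median SD of the 19 members used was 1.22 against 0.43 for random lists (above every one of 10000 random lists), and their mean pairwise r was 0.80, also above every random list. The score ran from -1.27 in patient 8 to 1.83 in patient 5, an 8.53-fold range, with patient 9 at 1.46 and patient 4 at 0.97. RSAD2, which restricts virus budding, had a mean of 7.73 ± 1.84 (SD, n = 9), IFI44L 7.76 ± 1.68, ISG15, a ubiquitin-like modifier, 8.45 ± 1.38, and XAF1 had the smallest SD of the list, 8.48 ± 0.76. Adjusted over the list alone, 8 members passed limma's test of excess spread (IFI44L, IFI44, IFIT1, RSAD2, ISG15, OAS3, IFI27 and CMPK2), and 0 passed over all genes.

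B cell genes had the widest range of any lymphocyte list. Their score ran from -1.96 in patient 1 to 1.83 in patient 9, a 13.8-fold range, with a median SD of 1.18 and a mean pairwise r of 0.87 over 9 members, both above every random list. MS4A1, which encodes CD20, had a mean of 8.48 ± 1.88 (SD, n = 9) and TCL1A, a gene of naive B cells, 7.12 ± 1.94 (SD 1.18 without patient 1), and both passed limma's test adjusted over the list alone, with 0 over all genes. CD22 had the smallest SD, 5.23 ± 0.74. Genes of T cells varied less, with a median SD of 0.80 and a mean pairwise r of 0.63 over 12 members, and the score ran from -1.24 in patient 7 to 1.16 in patient 4. CD27, a costimulatory receptor, had the largest SD (9.20 ± 0.96) and CD5 the smallest (6.21 ± 0.55). The cytotoxic and NK list had a median SD of 1.12 and a mean pairwise r of 0.51 over 11 members, and its score ran from -1.57 in patient 8 to 1.17 in patient 3. GZMH, a granzyme, stood at 8.05 ± 1.90 and GZMA at 7.50 ± 0.85. Each of these medians and correlations exceeded every random list, and 0 T cell and 0 cytotoxic genes passed in limma, over all genes or adjusted over the list alone.

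Genes of antibody-secreting cells were few at the level used. Both members of the plasma cell list, JCHAIN (7.38 ± 2.52) and MZB1, a chaperone of antibody secretion (5.60 ± 1.61, SD, n = 9), passed limma's test adjusted over the list alone, with 0 over all genes, and no score was formed. TYMS, the thymidylate synthase of dividing cells, was the only 1 of 15 proliferation genes at the level minimum (5.23 ± 1.74). Its limma p was 0.00622, with an adjusted p of 0.951 over all genes. Its values ran from 3.37 to 8.25, so patients with high values helped it reach the minimum. That p is therefore no call for the proliferation list. Eosinophil (CLC, 9.80 ± 1.13), basophil (FCER1A, 6.09 ± 1.07) and dendritic cell lists (CD1C, 6.01 ± 0.67) had 2 members each, with 0 passing in limma.

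Granule genes of immature neutrophils had the largest list spread, a median SD of 2.28 over the 3 members used (LTF, LCN2 and CAMP, 6.18 ± 1.35, SD, n = 9), all of which passed limma's test adjusted over the list alone, with 0 over all genes. Their score ran from -1.85 in patient 5 to 3.08 in patient 1, with patient 7 at 2.39, a 30.6-fold range. Of the 13 genes fixed for this list, 9 of those measured had means below the level minimum, so the score rests on few genes. Genes of mature neutrophils varied less. Their median SD was 0.62 (percentile 98.7) and their mean pairwise r 0.62 over 10 members, with ALPL, a phosphatase of mature neutrophils, at 6.20 ± 1.17 and the chemokine receptor CXCR2 at 9.35 ± 0.52. The score ran from -0.94 in patient 9 to 0.85 in patient 7.

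Monocyte genes were highest in patient 7. The score there was 1.98, against 0.19 in the next patient (patient 5) and -1.05 in the lowest (patient 4). The median SD was 0.88 (percentile 99.99) and the mean pairwise r 0.71 over 9 members. CD163, a haemoglobin scavenger receptor, had a mean of 5.87 ± 1.69 (SD, n = 9; SD 0.79 without patient 7), CD14 10.54 ± 1.04 and LYZ, lysozyme, 13.19 ± 0.48. A lower-level probe set of LYZ had an SD of 2.29 and followed the first one (r = 0.89, exact permutation p = 0.000430, adjusted p = 0.00307), so the size of the spread of this gene depends on the probe set. The monocyte score ran opposite to spike-in level (r = -0.72, exact permutation p = 0.00231, adjusted p = 0.0370 over 16 lists; rho = -0.92, exact permutation p = 0.00131, adjusted p = 0.0210). Without the 2 arrays farthest in spike-in level r was -0.58 (exact permutation p = 0.0575), so the call was lost without them, and scaling moved it. With each array centred on its median r was -0.66 (exact permutation p = 0.0146, adjusted p = 0.233), and after quantile normalization it was -0.74 (exact permutation p = 0.00163, adjusted p = 0.0261) with rho -0.88 (exact permutation adjusted p = 0.0492). The other 15 lists did not pass against spike-in level, for r or for rho.

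Erythroid and platelet genes also varied more than random lists, with median SDs of 0.90 and 1.09 and mean pairwise r of 0.60 and 0.85, each above every random list. CA1, the carbonic anhydrase of red cells, had a mean of 9.17 ± 1.84 (SD, n = 9) and DMTN, a red cell membrane skeleton protein, 9.23 ± 0.42. The erythroid score was highest in patient 1 (1.54) and lowest in patient 7 (-0.87). TREML1, a platelet granule receptor, stood at 7.07 ± 1.43 (SD 0.63 without patient 3) and SELP, P-selectin, at 5.28 ± 0.64, and the platelet score ran from -2.22 in patient 3 to 1.16 in patient 9. In limma, 0 genes of either list passed, over all genes or adjusted over the list alone.

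Glucocorticoid-responsive genes separated patients 7 and 2 from the others. The score was 1.87 in patient 7 and 1.37 in patient 2, and lay between -0.96 and -0.21 in the other 7 patients. IL1R2, a decoy receptor for interleukin 1, had a mean of 8.97 ± 1.73 (SD, n = 9), FKBP5, a chaperone of the glucocorticoid receptor, 9.38 ± 1.39, and ZFP36, which speeds mRNA decay, 10.65 ± 0.43. The median SD of the 10 members was 1.10 and the mean pairwise r 0.72, both above every random list, and 0 members passed limma's test over all genes or adjusted over the list alone. The 4 NFAT cytokine genes measured, IL2 (2.35), IFNG (2.39), TNF (2.64) and IL4 (2.35), had values under 3 on all 9 arrays, near the lowest value of the arrays, so no spread can be read from them.

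Reference genes were the 1 list with less spread than most random lists. They had a median SD of 0.31, at percentile 2.43 of random lists, with HPRT1 the most variable (6.54 ± 0.76, SD, n = 9). Ribosomal protein genes, which have many pseudogene copies, had a median SD of 0.43 (percentile 50.5), with RPL8 at 12.39 ± 0.52 and RPS3 at 12.99 ± 0.27, yet moved together with a mean pairwise r of 0.77. MHC class II pathway genes had a median SD of 0.55 (percentile 89.4) and a mean pairwise r of 0.65, with HLA-DOB at 6.54 ± 1.36. Oxidative phosphorylation genes had a median SD of 0.60 (percentile 96.9) and a mean pairwise r of 0.67, with COX7B at 6.42 ± 0.99. Immediate early genes, which respond within minutes to handling or activation, had a median SD of 0.76 (percentile 99.5) and a mean pairwise r of 0.46, with FOS at 7.21 ± 0.90 (SD 0.54 without patient 4). Heat shock genes had a median SD of 0.61 (percentile 89.4) and a mean pairwise r of 0.32 (percentile 90.4), with HSPH1 at 5.74 ± 0.86. In limma, 0 genes of these 6 groups passed over all genes or adjusted over the list alone. Of the 16 lists, 12 exceeded the 95th percentile of random lists in spread and 15 in coherence.

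**Figure D2:**
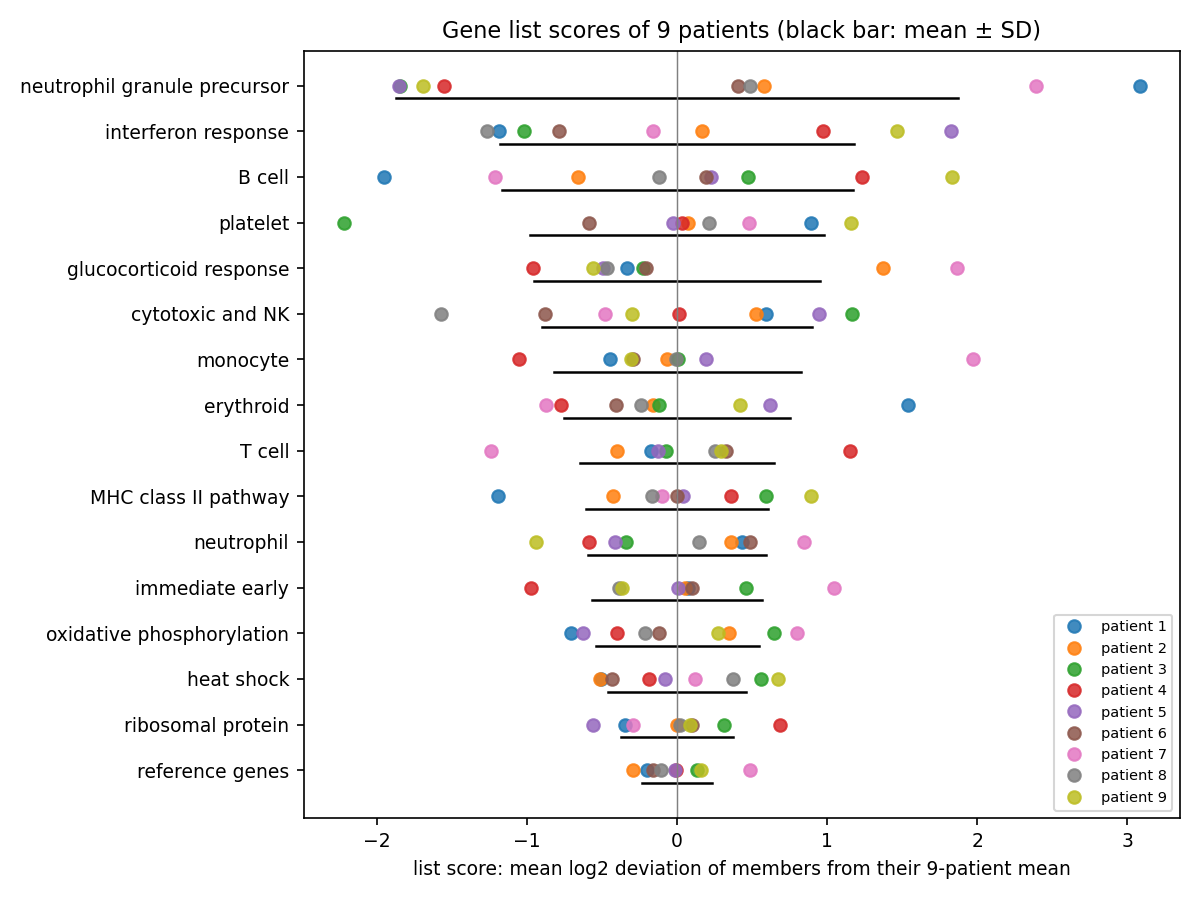
Scores of the 16 gene lists (horizontal axis, mean log2 deviation of the members from their mean over 9 patients), 1 point per patient, with a black bar under each list for the mean ± SD over the 9 patients. Granule precursor genes span -1.85 to 3.08, and reference genes span -0.29 to 0.49.

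Neutrophil and B cell scores ran in opposite directions. Pearson's r was -0.86 (exact permutation p = 0.00273, adjusted p = 0.0150 over 11 pairs, n = 9) and rho was -0.85 (exact permutation p = 0.00607, adjusted p = 0.0334). Patients 9 and 4 had the lowest neutrophil and the highest B cell scores. Without these 2 patients r was -0.67 (exact permutation p = 0.0877), so the call was lost without them. It was also lost without patient 2 (r = -0.85, exact permutation adjusted p = 0.0584), patient 4 (r = -0.83, 0.0821) or patient 9 (r = -0.78, 0.0906) alone, with fewer patients in the test. Within the 6 arrays of lower spike-in level r was -0.90 (exact permutation p = 0.0167), and the other 3 arrays were too few for a value.

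Glucocorticoid-responsive genes ran opposite to T cell genes. Pearson's r was -0.85 (exact permutation p = 0.00166, adjusted p = 0.0150, n = 9), while rho was -0.67 (exact permutation p = 0.0589, adjusted p = 0.130). The pooled r spans 2 separate sets of glucocorticoid scores, since patients 2 and 7 stood apart. Over the other 7 patients r was -0.79 (exact permutation p = 0.119), so the call was lost without patients 2 and 7. It was also lost without patient 2 (r = -0.89, exact permutation adjusted p = 0.0584), patient 4 (r = -0.87, 0.0821) or patient 7 (r = -0.72, 0.0810) alone. Patient 4 had the lowest glucocorticoid score (-0.96) and the highest T cell score (1.16). The rest of those 7 patients lay between -0.56 and -0.21 in glucocorticoid score and between -0.18 and 0.32 in T cell score. Among them the highest glucocorticoid score (patient 6) went with the highest T cell score, and the lowest (patient 9) with 0.30. The r over those 7 patients therefore leaned on patient 4, and an r without patients 2, 4 and 7 together was not computed. Within the 6 arrays of lower spike-in level r was -0.94 (exact permutation p = 0.181) and rho -0.26 (exact permutation p = 0.658). These 6 included patient 7, with scores of 1.87 and -1.24, while the others of the 6 had glucocorticoid scores between -0.56 and -0.21. The r of -0.94 thus rests on patient 7 and does not show the relation within that set.

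The other 9 pairs did not pass on Pearson's r. Glucocorticoid and neutrophil scores had r = 0.69 (exact permutation p = 0.0171, adjusted p = 0.0626) and rho = 0.87 (exact permutation p = 0.00451, adjusted p = 0.0334), and r = 0.60 (exact permutation p = 0.145) without patients 2 and 7. Under 10 alternative settings the exact permutation adjusted p of this pair lay between 0.00934 and 0.140, and it passed under 7 of them. T cell scores had r = 0.67 with B cell, -0.64 with neutrophil and 0.69 with ribosomal protein scores (each with an exact permutation adjusted p of 0.102), with rho of 0.73, -0.53 and 0.75 (exact permutation adjusted p = 0.0856, 0.270 and 0.0856). Without the 2 farthest patients these r were 0.58, -0.48 and 0.58 (exact permutation p = 0.171, 0.250 and 0.215), and the ribosomal protein r was 0.42 without patient 4 alone. Neutrophil and monocyte scores had r = 0.55 and rho = 0.32 (exact permutation adjusted p = 0.141 and 0.564), and r = 0.18 without patient 7. Erythroid scores had r = 0.31 with platelet scores and -0.15 with neutrophil scores, T cell and cytotoxic scores had r = -0.14 and rho = -0.28, and interferon and monocyte scores had r = -0.09. The exact permutation adjusted p of these last 4 lay between 0.546 and 0.947. The T cell and cytotoxic r was -0.76 (exact permutation p = 0.0579) without patients 4 and 7, and -0.45 without patient 7 alone. Erythroid and neutrophil scores had r = -0.56 (exact permutation p = 0.192) without patients 1 and 5. B cell and plasma cell scores could not be compared, as the plasma cell list had fewer than 3 members at the level minimum.

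**Figure D3:**
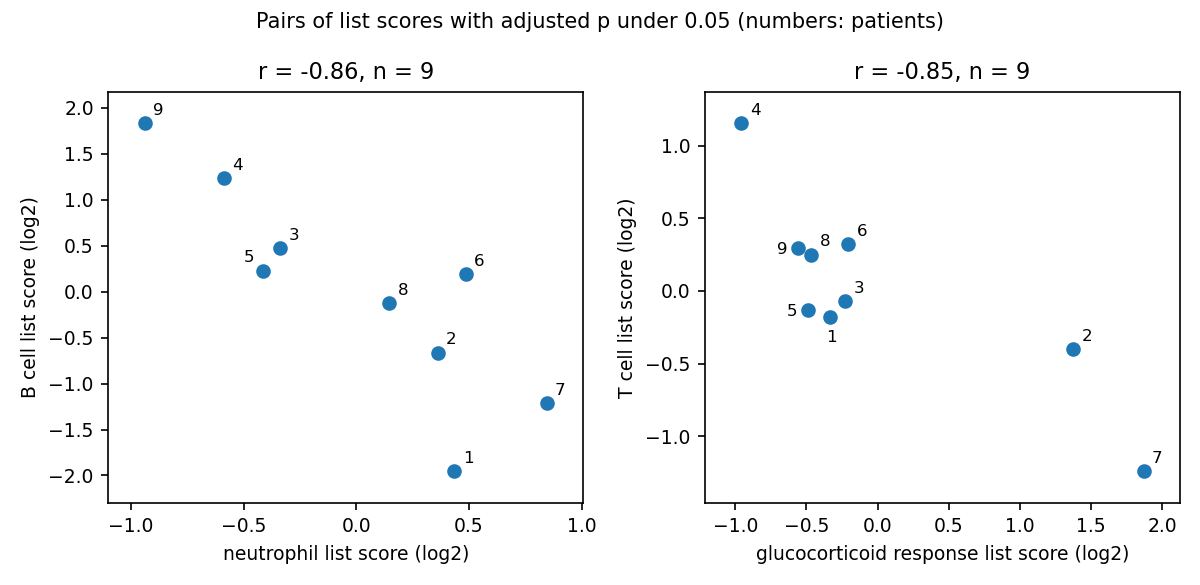
List scores (log2) of the pairs with an adjusted p under 0.05, 1 numbered point per patient. Left, neutrophil (horizontal) against B cell (vertical) scores, r = -0.86; right, glucocorticoid response (horizontal) against T cell (vertical) scores, r = -0.85, with patients 2 and 7 apart at 1.37 and 1.87 on the horizontal axis.

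RNA integrity did not pass as a correlate of any of the 16 scores over the 9 patients. The 3' minus 5' difference ran from 0.17 in patient 7 to 1.40 in patient 9. The lowest exact permutation adjusted p was 0.716 for r and 0.590 for rho, the latter for the monocyte score (r = -0.45, exact permutation p = 0.138; rho = -0.72, exact permutation p = 0.0369). Without the 2 patients farthest in RNA integrity r was -0.85 for the monocyte score (exact permutation p = 0.0123) and 0.82 for the T cell score (exact permutation p = 0.0306, against r = 0.32 over all 9), neither adjusted over the lists.

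A gene's own probe sets gave a check of its spread. Among 2346 genes with 2 probe sets at the level minimum, the median r between them over the 9 patients was 0.71, and 1055 genes (45.0%) passed the exact permutation test after adjustment, 6 of them with a negative r. With patients shuffled, 0 genes passed and the median r was -0.00019. The share that passed was 22.5% among the genes with an SD of 0.07 to 0.31 and 68.1% among those with an SD of 0.57 to 2.28. IL1R2 (r = 0.998), PI3 (0.995), CD163 (0.980), TCL1A (0.958), XAF1 (0.954) and CD5 (0.804) passed, whereas HSPH1 did not (r = 0.696, exact permutation adjusted p = 0.0787). All 7 interferon genes and all 4 B cell genes with 2 probe sets passed, against 1 of 3 erythroid genes. Without the _x_at and _s_at sets, which can share targets, 265 of 857 genes passed. Probe sets on 1 array share the RNA and the hybridization, so this agreement covers probe error and not differences between arrays.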

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

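The tests of patient 7's monocyte score were written down before their results were seen, although the pattern itself was found in these data. Among 65 values tested for a patient far from the others, 7 had a gap to the nearest patient that exceeded Dixon's limit, where chance gives about 1 in 20 for values not picked by their spread. Of these 7, 5 are genes named for their large SD, which a single far patient raises, and CD163 is also part of the monocyte score, so the 7 values cannot be set against a chance count.

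The monocyte score of patient 7 was 1.98, against 0.19 in the next patient, and CD163 in the same patient was 9.91, against 6.39. As deposited, the score lay 5.44 prediction SE above the other 8 patients. It lay 4.65 SE above them after quantile normalization, 4.45 SE after prediction from RNA integrity and 5.51 SE after prediction from spike-in level. Patient 7 had the lowest spike-in mean (9.15, next 9.30) and the lowest 3' minus 5' difference (0.17, next 0.34). Both predictions thus reach beyond the range of the other 8 patients. Taken singly, the values argue against array scale, and less firmly against RNA integrity and hybridization, as the whole cause. These measures were not removed together, and the score did run opposite to spike-in level over the 9 patients. Patient 7 was also highest in the glucocorticoid (1.87), immediate early (1.05), neutrophil (0.85), oxidative phosphorylation (0.80) and reference gene (0.49) scores, and lowest in the T cell (-1.24) and erythroid (-0.87) scores. The excess was 2.22 on the log2 scale as deposited and 1.78 after spike-in level. No biological explanation was tested, since the labels name none, and the source of the excess stays open.

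CD177 was 12.84 in patient 7 and at most 7.14 in the others. TCL1A was 2.86 in patient 1, near the lowest value of the arrays, and at least 6.22 in the others. TREML1 was 3.58 in patient 3, with 6.72 the next lowest. FOS was 5.22 in patient 4, with 6.85 the next lowest. The 3' control probe set for 18S ribosomal RNA was 12.81 in patient 4, against 8.20 in the next patient, and this patient also had the highest spike-in mean, 10.42.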

How the results depend on the processing

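The spike-in covariate and the probe set agreement were chosen after seeing the data, and the other alternatives were not. No paired analysis was possible because the labels give a single group. Excess spread gave 0 genes in limma under all 21 alternatives, which says nothing about stability, as the test recovered none of the simulated genes. Lists above the 95th percentile numbered 10 to 14 in spread and 12 to 18 in coherence over 7 settings, of 14 to 22 lists tested (14 and 18 of 22 with no level filter), and 11 to 12 and 14 to 15 with 1 patient left out, and no alternative gave a relation to RNA integrity.

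Over 10 settings the neutrophil with B cell r stayed between -0.87 and -0.77 (exact permutation adjusted p 0.0114 to 0.0295) and glucocorticoid with T cell between -0.87 and -0.77 (0.00934 to 0.0255). With 1 patient left out they ran from -0.92 to -0.78 and from -0.89 to -0.72. Between 0 and 2 pairs then passed: 0 without patient 2 or 4, and 1 without patient 7 (neutrophil with B cell) or 9 (glucocorticoid with T cell), where fewer patients weaken the exact test.

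After spike-in level 5 pairs passed, adding T with B cell (0.81), neutrophil with monocyte (0.70) and glucocorticoid with neutrophil (0.70). The last also passed at a level of at least 7 (0.78), with all probe sets averaged (0.76) and without _x_at and _s_at sets (0.68). It passed too with a pseudocount (0.71), after RNA integrity (0.73) and with median scores (0.69). Over the settings its exact permutation adjusted p ran from 0.00934 to 0.140. Ribosomal protein with T cell passed after quantile normalization (0.84). Signs turned in 3 pairs that did not pass. T cell with cytotoxic had 0.046 without _x_at and _s_at sets. Erythroid with neutrophil had 0.020 after centring, and -0.57 to 0.12 with 1 patient left out, positive without patient 7. Interferon with monocyte had 0.11 after RNA integrity and 0.070 with median scores. That pair ran from -0.18 to 0.071 with 1 patient left out, positive without patient 4. Genes whose probe sets agreed fell from 1055 to 265 without _x_at and _s_at sets, where 857 instead of 2346 genes were tested. The share that passed there was 30.9%, against 45.0% in the main setting. With 1 patient left out these genes numbered 784 to 977. For these changes, other than fewer genes or patients, the cause was not tested. On 31.3% to 34.0% of the probe sets of an array the signal did not exceed the floor, which limits low-level lists.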

Other observations

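For the glucocorticoid and T cell relation, leaving out patient 7 and removing RNA integrity were planned, but what they would show was set down only after the result was seen. Chosen only after the result was seen were the removal of spike-in level and of the neutrophil and monocyte scores from that relation, and the members used for the plasma cell and proliferation relation.

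Of the 50 genes with the largest SD, 16 were in a fixed list and 34 were not. Of these 34, 7 (20.6%) had an r of at least 0.8 with the plasma cell score over all measured members, against 0.577% of all genes: IGLC1, IGLL5, IGLL3P, IGKC, IGHM, MLIP and BMS1P20, of which IGLC1, IGLL5 and IGLL3P have lambda light chain sequence in common, and how specific the probe sets are was not checked. Another 5 (14.7%, against 7.50% of all genes) had an r of at least 0.8 with the monocyte score, among them CYP1B1, an enzyme that oxidises steroids and xenobiotics (r = 0.97), and VNN1, a pantetheinase (r = 0.94). With the proliferation score, 7 of the 34 (20.6%, against 0.811% of all genes) also had an r of at least 0.8. Over all measured members the proliferation and plasma cell scores had r = 0.967, so the like count is no separate result. It cannot tell which of these scores the genes follow. BLNK, a B cell signalling adaptor, had r = 0.95 with the B cell score, and PASK, a kinase, r = 0.93 with the T cell score. MMP9 and S100A12, products of neutrophils, had r = 0.90 and 0.87 with the neutrophil score. These genes were picked for their spread, and the correlations across 9 patients were not tested one by one.

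Over 5 plasma cell genes, which mark antibody-secreting cells, and 15 proliferation genes, patients 8 and 9 had plasma cell scores of 1.89 and 2.17 and proliferation scores of 1.04 and 1.51, with at most 0.41 and -0.01 in the other 7 patients. The scores had r = 0.967 (exact permutation p = 0.000419) and rho = 0.783 (exact permutation p = 0.0172). Over JCHAIN, MZB1 and TYMS, the genes at the level minimum, r was 0.930 (exact permutation p = 0.00285) and rho 0.70 (exact permutation p = 0.0433). Over the 7 patients without 8 and 9 these genes gave r = 0.663 (exact permutation p = 0.110). All members gave r = 0.872 (exact permutation p = 0.0302) in those 7. Members on no array at the lowest value gave r = 0.873 (exact permutation p = 0.0278) but rho = 0.536 (exact permutation p = 0.236). How far the relation rests on patients 8 and 9 therefore depends on the genes and the measure used. Over all members r was 0.981 after removal of spike-in level and 0.958 after removal of RNA integrity, and over the genes at the level minimum 0.932 and 0.914 (exact permutation p = 0.00970 and 0.00124), which argues against both as the whole cause. Cycling antibody-secreting cells, or plasmablasts, may contribute both sets of transcripts, but the relation is the pattern itself and cannot be told apart from other cycling cells in the same patients.

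The opposition of glucocorticoid-responsive and T cell genes remains open. It held after removal of RNA integrity (r = -0.86, exact permutation adjusted p = 0.0240) and of spike-in level (r = -0.87, exact permutation adjusted p = 0.0206), which argues against both as the whole cause. After the neutrophil and monocyte scores were removed r was -0.44 (exact permutation p = 0.240), so a larger share of myeloid cells, which express IL1R2, could account for part of it and cannot be told apart at 9 patients. Without patient 7 r was -0.72 (exact permutation adjusted p = 0.0810), which leaves the weight of that patient open too. Among the patients other than 2 and 7, the opposition came mainly through patient 4.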
